A study of Arabidopsis thaliana with 12 samples.

How the data were processed

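The study measured transcripts of Arabidopsis thaliana cotyledons on Affymetrix ATH1 arrays, 1 array per sample and 12 in all: the wild type Ws-2 and the mutants clv1.12 and clv1.13, each treated with water or inoculated with Hyaloperonospora arabidopsidis Emwa1 at 40000 spores per ml when 10 days old, with 2 biological replicates per group. Plants grew at 20 °C with 12 h of light per day, and total RNA was taken 3 days after treatment. The deposited values are log2 expression per probe set, made comparable between arrays by the authors. The labels name Affymetrix Power Tools without a version or an algorithm. Values carry 2 decimals and run from 2.4 to 14.16, with near-identical quartiles on every array. No detection call or spread of probes within a probe set is deposited, so the depth behind a value is unknown, and the number of arrays limits the precision.

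Samples were grouped by genotype and treatment. The deposited log2 values of 22746 probe sets were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group, all 12 arrays, 6 residual degrees of freedom), and 64 control probe sets were left out. There were 13 contrasts: infection in each genotype and in their mean, each clv1 allele and the mean of both against Ws-2 in each treatment, clv1.13 against clv1.12 in each treatment, and the infection response of clv1 minus that of Ws-2. The tests are two-sided moderated tests, and p was adjusted by Benjamini-Hochberg within a contrast at a threshold of 0.05. These choices, the gene lists and the alternatives were made before the data were examined, apart from the additions named here and in the closing section.

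Replicate numbers are not stated to pair the arrays of a single experiment, so this was checked. Deviations of the replicate arrays from their group means were correlated across probe sets between the 6 groups, and the 15 correlations lay between 0.685 and 0.775. The replicate number was therefore taken to stand for the experiment. A further fit with the replicate number as a block (5 residual degrees of freedom) is printed beside each result whose call or count it changes, and the differences within each experiment beside the named genes and lists. The median residual standard deviation was 0.183 without and 0.144 with the block. Of 50 simulated changes of log2 1 each, the unblocked fit recovered 19 for infection in Ws-2 and 41 for the mean of the genotypes, and the blocked fit 49 and 50; of changes of log2 2 it recovered 45 and 49, and 50 and 50. False calls were 0 without the block and 9 and 11 with it, out of 22746 probe sets. Of changes of log2 0.5 the unblocked fit recovered 0 and 13 and the blocked fit 9 and 49. The simulated data were built with the additive experiment effect and the spread of the blocked fit. Its higher recovery therefore does not show that the experiment effect is additive in the real arrays.

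Probe sets were assigned to genes by the annotation deposited with the array platform, and names and gene order were taken from a RefSeq annotation, from which no coordinates are printed. Of the probe sets, 13513 are assigned to 1 gene, 503 to several and 8730 to none, which leaves 13355 distinct genes. An entry of a gene list counts as measured where the annotation assigns a probe set to it. Only 57 of the 394 entries (14.5%) of the 24 gene lists written before the data were examined are measured. Therefore 19 further lists were written after the coverage of the annotation was seen and before any contrast was computed. Of these 43 lists, 28 have at least 3 measured genes and were tested (10 of the former, 18 of the latter), 9 have fewer and 6 have 0. Lists were tested with limma camera (1 probe set per gene, the one of highest mean; preset correlation 0.01; Benjamini-Hochberg over the 28 lists in a comparison), and again with an estimated correlation. In 7 comparisons 29 of 196 tests passed with the preset correlation (26 in the blocked fit) and 0 with an estimated one (lowest adjusted p = 0.190).

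Genes were named by a rule. In infection in Ws-2, clv1 against Ws-2 in each treatment and the difference in response, the rule takes the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between the 2 sides, up to 4 members of smallest p of a list that passes, 2 of a list that does not, and the 5 genes of smallest p where fewer than 5 pass. CLV1 and PR1 were to be named always, but neither is assigned to a probe set here. After the data were seen, the rule was also applied to the blocked fit, where no overlap within an experiment is asked, and to the mean infection effect. Single-allele and single-mutant values are the largest called in the blocked fit.

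Shared genes were counted beside the number that independent lists give and that of 50 simulated data sets with no genotype effect, which keep the shared Ws-2 arrays. The simulated values are independent noise, and the sizes of the lists are not kept. The alternatives were the block, a filter on probe sets under the 40th percentile of mean expression, quantile normalization, eBayes with a trend and robust hyperparameters, only the arrays compared, an estimated list correlation, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.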

Results

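Transcripts of Arabidopsis thaliana cotyledons were measured on 12 Affymetrix ATH1 arrays. The plants were the wild type Ws-2 and the allelic mutants clv1.12 and clv1.13 of CLAVATA1 (CLV1), a receptor kinase best known for restricting the stem cell population of the shoot meristem. Cotyledons had been sprayed with water or with spores of Hyaloperonospora arabidopsidis isolate Emwa1, a biotrophic oomycete that causes downy mildew and is compatible with Ws-2, and were harvested 3 days later. Each of the 6 groups of genotype and treatment held 2 arrays, one from each of 2 independent experiments. The array medians lay between 5.68 and 5.8 on the log2 scale and the lower quartiles between 3.65 and 3.79. The number of arrays limits the precision of every value below. Differences are log2 differences of group means; an error after ± is the standard error of the fit without a block, with n = 2 arrays per group. A fit with the replicate number (experiment) as a block is called the blocked fit, the other the unblocked fit. Counts at an unadjusted p under 0.05 are those of the unblocked fit unless the blocked fit is named. With no effect anywhere, a share of 0.05 of the 22746 probe sets would reach it on average. The unblocked counts for infection, for the difference in response and for clv1.12 against Ws-2 in water lie below that share. So do those for clv1.13 against Ws-2 after inoculation (1099) and for clv1.13 against clv1.12 (722 and 786). The unblocked fit counts differences between the experiments as spread. In the blocked fit the counts lie above that share. They are 1287, 1443 and 1930 for infection in Ws-2, clv1.12 and clv1.13, and 2258 in their mean. They are 1160 for the difference in response and 2356 for clv1.12 in water. CLV1 itself and the salicylic acid markers PR1 and PR5 cannot be read here, because no probe set is assigned to them in the annotation available. Their signals may be among the 8730 probe sets assigned to no gene, so they are not shown to be unmeasured or unchanged.

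The infection response over the 3 genotypes asks which host transcripts change in a compatible downy mildew interaction. The lectin-like gene AT3G16530 rose by 4.95 ± 0.39 in the mean of the 3 genotypes, the plant defensin PDF1.2b by 4.06 ± 0.37 and AT5G14700 by 2.81 ± 0.22. The defensin gene LCR67 rose by 2.55 ± 0.30, the berberine bridge enzyme-like gene AT1G26380 by 2.43 ± 0.29, AT3G20340 by 2.61 ± 0.32 and the chitinase family gene AT2G43590 by 2.00 ± 0.25. These 7 genes passed in both fits, with adjusted p in the unblocked fit of 0.00394 for AT3G16530 and AT5G14700, 0.00639 for PDF1.2b and 0.0350 for the other 4. The differences within experiment 1 and experiment 2 were 4.89 and 5.01 for AT3G16530, 4.97 and 3.15 for PDF1.2b, 3.05 and 2.57 for AT5G14700, and 3.33 and 1.77 for LCR67. They were 2.93 and 1.93 for AT1G26380, 3.25 and 1.96 for AT3G20340, and 2.66 and 1.34 for AT2G43590. PDF1.2, a marker of the jasmonate and ethylene branch of defence, rose by 2.71 ± 0.41 in the blocked fit (adjusted p = 5.90e-05, unblocked 0.107; 3.53 and 1.89 within the experiments). AT1G19020 (2.08 ± 0.37) and the salicylic acid-responsive glutaredoxin GRX480 (0.94 ± 0.17) also rose in the blocked fit, with adjusted p = 1.00e-05 and 0.00269, against 0.192 and 0.195 unblocked. Falls were small. In the blocked fit BGLU46 (-0.40), AT3G43290 (-0.37) and AT5G43670 (-0.34) fell, with adjusted p = 0.0431, 0.0238 and 0.0413. None of these passed without the block (0.337, 0.198 and 1.00). BGLU46 lay between 3.36 and 4.14 on the 12 arrays, near their lower quartiles. In all, 17 probe sets rose and 0 fell in the unblocked limma fit (1004 at an unadjusted p under 0.05), against 220 and 9 in the blocked fit. With 1 array left out the unblocked count was 18 without Ws-2 inoculated replicate 2, 49 without clv1.12 inoculated replicate 2 and 5 to 9 without any of the other 10 arrays. The blocked count was 142 without Ws-2 water replicate 1, 131 without Ws-2 inoculated replicate 1, 132 without clv1.12 water replicate 1, 150 without clv1.12 inoculated replicate 1 and 149 without clv1.13 inoculated replicate 2, and 161 to 292 without any of the other 7. The call of AT3G20340, LCR67 and AT2G43590 ended in 10 of 12 such unblocked fits each, that of AT1G26380 in 9 and that of PDF1.2b in 1.

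**Figure D1:**
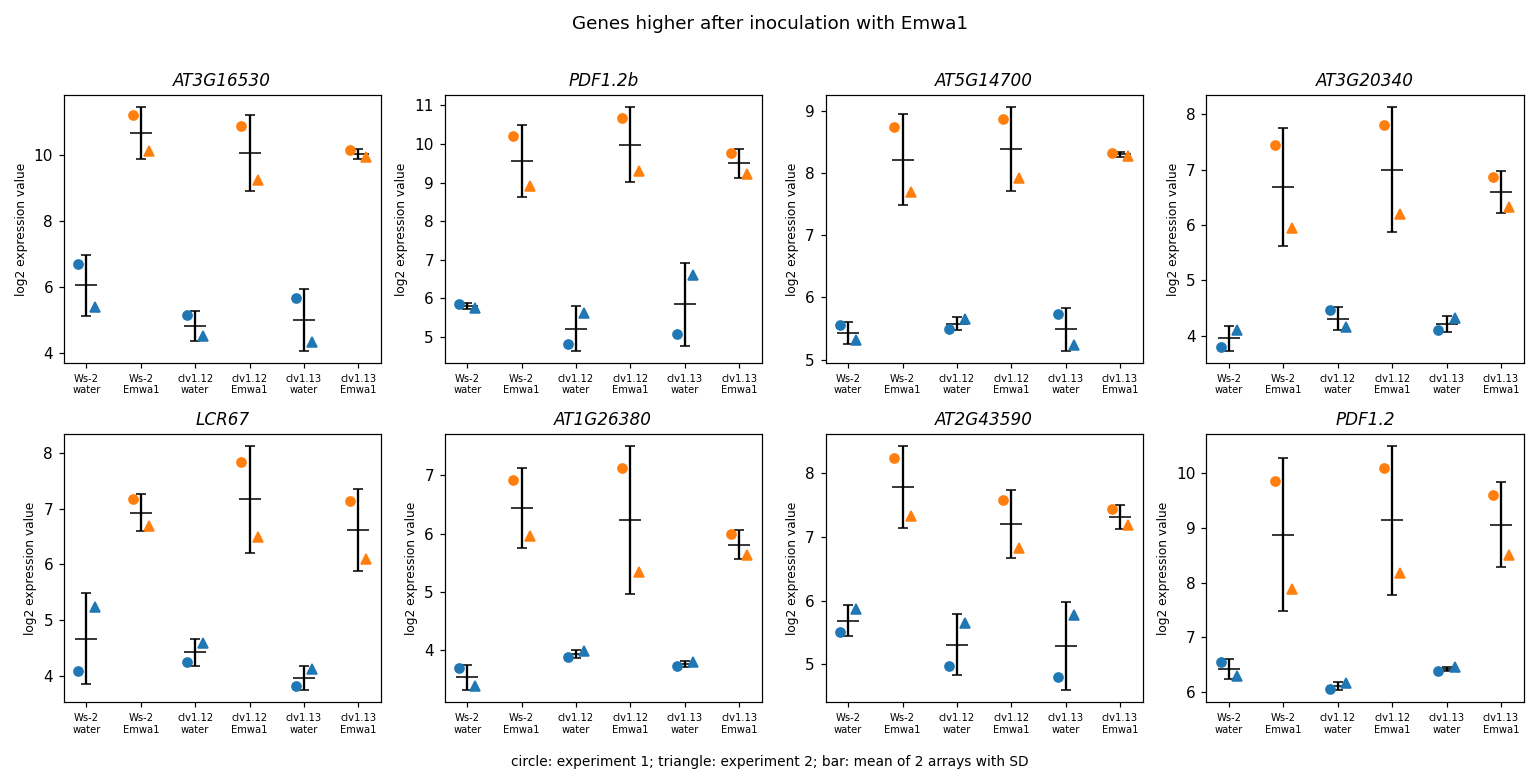
Log2 expression of infection-responsive genes on each of the 12 arrays, by genotype and treatment; circles are arrays of experiment 1 and triangles of experiment 2, blue for water and orange for Emwa1, and bars are the mean of 2 arrays with its SD. AT3G16530 averaged 6.07, 4.84 and 5.02 in the water groups of Ws-2, clv1.12 and clv1.13, and 10.66, 10.06 and 10.04 in their inoculated groups.

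In Ws-2 alone the infection contrast asks for the wild-type response, and no probe set passed in the unblocked limma fit (0 of 22746; 515 at an unadjusted p under 0.05). In the blocked fit 52 rose and 1 fell, of which 26 and 1 are assigned to a gene. AT3G16530 rose by 4.60 ± 0.67 (blocked adjusted p = 1.90e-06), PDF1.2b by 3.76 ± 0.63 (0.00741), AT1G26380 by 2.92 ± 0.51 (0.00186) and AT5G14700 by 2.79 ± 0.37 (1.76e-04). AT3G20340 (2.75), PDF1.2 (2.46), AT1G19020 (2.31) and the salicylic acid-inducible legume lectin gene AT5G03350 (2.29) rose in the same fit, with adjusted p of 0.00741, 0.0336, 0.00207 and 0.0296. The plastid ribosomal protein gene rps18 fell by 0.84 (0.0154). In experiment 1 and experiment 2 taken alone they were 4.50 and 4.70 for AT3G16530, 4.36 and 3.16 for PDF1.2b, 3.25 and 2.59 for AT1G26380, and 3.18 and 2.39 for AT5G14700. They were 3.66 and 1.83 for AT3G20340, 3.32 and 1.60 for PDF1.2, 2.56 and 2.05 for AT1G19020, 3.15 and 1.42 for AT5G03350, and -0.74 and -0.94 for rps18. Unblocked, the 5 genes of smallest p were AT3G16530, AT5G14700, AT2G18690 (1.46 ± 0.24, blocked adjusted p = 0.00206), PDF1.2b and AT1G26380, with adjusted p of 0.360, 0.360, 0.752, 0.752 and 0.856, none past the threshold. The blocked count was 6 without Ws-2 water replicate 1, 28 without Ws-2 water replicate 2, 7 without Ws-2 inoculated replicate 1 and 83 without Ws-2 inoculated replicate 2.

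Of the gene lists in infected Ws-2, a list of other defence-associated genes had a median of 0.81, with 14 of 15 measured members above 0 (0.89 and 0.39 within the experiments). It was higher by camera (adjusted p = 2.93e-09, blocked 8.16e-17), but adjusted p = 0.538 with an estimated correlation, and adjusted p = 0.0554 without Ws-2 inoculated replicate 1. AT1G26380 was the 1 member past the threshold adjusted over the list alone (8 in the blocked fit), and AT3G18250 (1.67), AT1G35710 (0.81) and AT1G13470 (0.61) followed. Plastid-encoded transcripts were lower by the same test. The median of 43 photosynthesis and energy genes was -0.23, with 3 above 0 (-0.22 and -0.31 within the experiments; adjusted p = 1.68e-12, blocked 3.72e-13, but 0.538 with an estimated correlation and 0.168 without Ws-2 water replicate 2). atpF was at -0.57, ndhE at -0.79, atpI at -0.57 and ndhH at -0.68. The median of 19 plastid ribosome and polymerase genes was -0.25, with 1 above 0 (-0.14 and -0.37 within the experiments; adjusted p = 3.47e-08, blocked 1.00e-07, but 0.538 with an estimated correlation). rps18 was at -0.84, rpoC2 at -0.54, rps19 at -0.39 and rpl33 at -0.38. The 25S ribosomal RNA control, a sign of which RNA was labelled, was 11.27 and 11.72 on the Ws-2 water arrays and 11.17 and 11.46 on the inoculated ones. The 3' minus 5' control signal was 2.13 and 2.33, and 2.33 and 2.24. The other 25 lists did not pass (adjusted p from 0.0764 to 0.843). Among them, the lists fixed before the data had medians of -0.30 for abscisic acid and dehydration (LTI30 -0.36, COR15B -0.60), -0.13 for the cell cycle (AUR3 -0.63, AUR2 -0.16), -0.01 for endoplasmic reticulum protein folding (BZIP60 0.31, AT5G07340 -0.19), 0.02 for the guard cell lineage (FMA 0.35, MUTE -0.10) and 0.14 for heat shock (ATHSP22.0 -0.22, AT5G48570 0.22). The medians were 0.09 for pattern-triggered immunity (BIK1 0.24, WRKY53 0.25), -0.12 for nuclear-encoded photosynthesis (SBPASE -0.15, PSBW -0.16), -0.03 for reference genes (AT4G34270 0.21, GAPC2 -0.08), 0.02 for root markers (EXPA18 0.15, PYK10 0.02) and -0.09 for sugar and amino acid transport (SWEET10 -0.09, SAG29 -0.22). In these 10 lists 0 members passed adjusted over the list alone in the unblocked limma fit, and 1 cell cycle member was lower in the blocked fit.

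Over the 3 genotypes 5 lists were higher by camera, none with an estimated correlation. The other defence-associated genes had a median of 0.38 (0.52 and 0.40 within the experiments; adjusted p = 4.19e-07, but 0.416 with an estimated correlation), with 1 member risen in the unblocked and 5 in the blocked fit; AT1G26380 rose in both, and AT3G18250 (1.01) and AT5G52760 (1.07) in the blocked fit. Pattern-triggered immunity genes had a median of 0.07, with 5 of 5 above 0 (adjusted p = 0.0255, but 0.241 with an estimated correlation and 0.0596 in the blocked fit). The Aux/IAA genes, repressors of auxin signalling, had a median of 0.09 (adjusted p = 0.0231, but 0.314 with an estimated correlation), and the UDP-glycosyltransferases 0.02 (adjusted p = 0.0231, but 0.241 with an estimated correlation). Expansins and xyloglucan hydrolases had a median of -0.01 and a mean of 0.05 and tested as higher (adjusted p = 0.0429, but 0.241 with an estimated correlation and 0.190 in the blocked fit). Medians within experiment 1 and experiment 2 were 0.14 and 0.06 for pattern-triggered immunity, 0.12 and 0.10 for Aux/IAA, 0.05 and -0.01 for UDP-glycosyltransferases and 0.01 and 0.05 for expansins.

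The mutants were compared in the same way. In clv1.12, AT3G16530 rose by 5.23 ± 0.67, PDF1.2b by 4.77 ± 0.63, PDF1.2 by 3.03 ± 0.72 and AT5G14700 by 2.82 ± 0.37 in the blocked fit (adjusted p = 3.68e-07, 9.40e-04, 0.00779 and 1.51e-04). In clv1.13, AT3G16530 rose by 5.02 ± 0.67, PDF1.2b by 3.66 ± 0.63, AT5G14700 by 2.82 ± 0.37 and LCR67 by 2.65 ± 0.52 (blocked adjusted p = 6.17e-07, 0.0150, 2.17e-04 and 0.0405). Within experiment 1 and experiment 2 the differences were 5.71 and 4.74 for AT3G16530, 5.86 and 3.67 for PDF1.2b, 4.04 and 2.01 for PDF1.2 and 3.37 and 2.27 for AT5G14700 in clv1.12. In clv1.13 they were 4.46 and 5.58 for AT3G16530, 4.69 and 2.62 for PDF1.2b, 2.60 and 3.04 for AT5G14700, and 3.32 and 1.97 for LCR67. The unblocked limma fit called 0 probe sets in either mutant (623 and 893 at an unadjusted p under 0.05), the blocked fit 41 and 19, all higher. Plastid-encoded lists were higher in infected clv1.12. The photosynthesis and energy genes had a median of 0.34 (0.21 and 0.43 within the experiments; adjusted p = 3.20e-21, but 0.402 with an estimated correlation), and the ribosome and polymerase genes 0.36 (0.30 and 0.43; adjusted p = 3.10e-14, but 0.190 with an estimated correlation). The 25S ribosomal RNA control was 11.57 and 11.64 on the clv1.12 water arrays and 11.91 and 11.82 on the inoculated ones, and the 3' minus 5' control signal, a sign of RNA quality, 2.23 and 2.24 against 2.66 and 2.60. In infected clv1.13 those plastid medians were 0.00 and -0.07, neither past the threshold. The other defence-associated genes were higher in clv1.12 (median 0.32; 0.58 and 0.13 within the experiments; adjusted p = 1.71e-04, but 0.478 with an estimated correlation and 0.632 without clv1.12 inoculated replicate 1), and had a median of 0.03 in clv1.13 (adjusted p = 0.524). Cytosolic ribosomal protein genes tested as higher in clv1.12 (median 0.01; 0.05 and -0.04 within the experiments; adjusted p = 0.0396, but 0.929 with an estimated correlation, 0.114 in the blocked fit and 0.965, with the direction turned, after quantile normalization). In clv1.13 their median was 0.09 (0.04 and 0.08; adjusted p = 0.00177, but 0.887 with an estimated correlation, 0.0714 after quantile normalization and 0.715, with the direction turned, without clv1.13 water replicate 2).

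In water-treated cotyledons, the comparison of both clv1 alleles with Ws-2 asks what the mutations do without the pathogen. ECS1, which encodes a cell wall-associated protein, fell in the mean of the alleles (-2.96 ± 0.43), and so did the glutaredoxin family gene AT3G62950 (-2.56 ± 0.68). AT1G33340 (-2.22 ± 0.40), AT3G46880 (-1.84 ± 0.44) and the TRAF-like gene ZW9 (-1.75 ± 0.30) also fell. CLV3, the precursor of the peptide ligand of CLV1, rose by 0.78 ± 0.18 and the endoglucanase family gene GH9B8 by 1.09 ± 0.24. All 7 passed in the blocked fit alone, with adjusted p = 3.34e-04 for ECS1, 5.69e-06 for AT3G62950, 0.0130 for AT1G33340, 0.0135 for AT3G46880, 0.00275 for ZW9, 0.0187 for CLV3 and 0.00357 for GH9B8. In the same order their unblocked adjusted p was 0.187, 0.675, 0.456, 0.620, 0.376, 0.571 and 0.571. AT3G47250 (-1.09), AT2G33850 (-1.05), AT5G59080 (-1.03) and GLC (-0.74) fell in the blocked fit alone as well, and AT3G25570, which encodes an S-adenosylmethionine decarboxylase (1.19), AT2G38180 (0.74) and AT5G42250 (0.63) rose there. Within experiment 1 and experiment 2 the differences were -3.25 and -2.66 for ECS1, -2.53 and -2.60 for AT3G62950, -1.53 and -2.90 for AT1G33340, -1.47 and -2.22 for AT3G46880, and -2.25 and -1.26 for ZW9. They were 0.80 and 0.77 for CLV3, 1.04 and 1.14 for GH9B8 and 0.58 and 1.79 for AT3G25570. Mean ECS1 expression was 6.52 ± 0.52 (SD, n = 2) in Ws-2, 3.64 ± 0.13 in clv1.12 and 3.49 ± 0.08 in clv1.13, so the mutants lay near the lower quartile of the arrays. CLV3 was as low, at 3.27 ± 0.21 in Ws-2, 4.02 ± 0.37 in clv1.12 and 4.07 ± 0.00 in clv1.13. It is also the only measured gene of the list of shoot apex and leaf primordia markers, so its rise does not exclude more of that tissue in the mutant samples. POL, the other measured member of the CLAVATA list, differed by -0.08 ± 0.18. Of all probe sets, 4 fell and 0 rose in the unblocked limma fit (1426 at an unadjusted p under 0.05), none assigned to a gene, against 47 lower and 14 higher in the blocked fit. Of these 4, 1 was at -2.56 ± 0.16 (unblocked adjusted p = 0.00150). Its difference between clv1.13 and clv1.12 was -4.95, so its fall in the mean of the alleles rests mostly on clv1.13. Another was at -2.185 ± 0.23 (0.0296). Both were chosen after their values were seen. The 5 genes of smallest p in the unblocked fit (ECS1, AT2G33850, AT3G47250, ZW9 and GLC; adjusted p = 0.0733 to 0.376) did not pass. Without 1 water array the unblocked count was 0 or 1, and the blocked count ran from 20 (without clv1.12 water replicate 1) to 108 (without clv1.12 water replicate 2), with 21 and 26 without Ws-2 water replicates 1 and 2 and 28 without clv1.13 water replicate 2.

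Lists of ribosomal, photosynthesis, cell cycle and plastid-encoded genes were lower in water-treated clv1 by camera, and none held with an estimated correlation. Nuclear-encoded chloroplast ribosomal proteins had a median of -0.26 with 0 of 9 above 0 (adjusted p = 7.18e-07, but 0.452 with an estimated correlation). AT3G13120 was at -0.31, AT5G47190 at -0.40, AT5G65220 at -0.24 and AT1G64510 at -0.30. Nuclear-encoded photosynthesis genes had a median of -0.14 with 0 of 10 above 0 (adjusted p = 0.00985, but 0.638 with an estimated correlation, 0.248 after quantile normalization and 0.524 without Ws-2 water replicate 2). LHCB4.3 was at -0.59, SBPASE at -0.22, PSAE-1 at -0.16 and PSBY at -0.23. The 4 cell cycle genes had a median of -0.33 (adjusted p = 0.00745, but 0.452 with an estimated correlation, 0.136 without Ws-2 water replicate 1 and 0.147 without clv1.12 water replicate 1). AUR2 was at -0.43, AUR1 at -0.40, PRL at -0.27 and AUR3 at -0.01, with 0 past the threshold adjusted over the list alone in the unblocked limma fit and 2 in the blocked fit. Cytosolic ribosomal proteins had a median of -0.08 with 41 of 117 above 0 (adjusted p = 8.13e-06, but 0.591 with an estimated correlation, 0.278 after quantile normalization and 0.442 without Ws-2 water replicate 1). Plastid-encoded ribosome and polymerase genes had a median of -0.16 with 3 of 19 above 0 (adjusted p = 3.36e-05, but 0.452 with an estimated correlation and 0.209 without Ws-2 water replicate 2). rpoC2 was at -0.55, rpoA at -0.54, rps18 at -0.52 and rps19 at -0.40. These means rest mostly on clv1.13: in clv1.12 and clv1.13 taken alone, rpoC2 was at -0.33 and -0.77, rpoA at -0.23 and -0.85, rps18 at 0.05 and -1.08, and rps19 at -0.04 and -0.77. Plastid-encoded photosynthesis and energy genes had a median of -0.05 (adjusted p = 0.0108, but 0.718 with an estimated correlation, 0.608 after quantile normalization and 0.291, with the direction turned, without Ws-2 water replicate 2). The 25S ribosomal RNA control was 11.27 and 11.72 on the Ws-2 water arrays, 11.57 and 11.64 on those of clv1.12 and 11.09 and 11.11 on those of clv1.13. Within experiment 1 and experiment 2 the medians were -0.22 and -0.27 for chloroplast ribosomal proteins, -0.23 and -0.11 for photosynthesis, and -0.53 and -0.14 for the cell cycle. They were -0.09 and -0.06 for cytosolic ribosomal proteins, -0.17 and -0.23 for plastid ribosome and polymerase genes, and 0.04 and -0.23 for plastid photosynthesis and energy genes. The other 22 lists did not pass (adjusted p from 0.0798 to 0.996). Those fixed before the data had medians of -0.05 for abscisic acid and dehydration (LTI30 -0.34, COR47 -0.18), -0.16 for endoplasmic reticulum folding (CRT1b -0.17, AT5G07340 -0.21), -0.13 for the guard cell lineage (SPCH -0.20, FMA -0.10), and 0.03 for heat shock (AT1G53540 0.21, AT5G48570 0.03). They were -0.19 for pattern-triggered immunity (WRKY6 -0.46, EFR -0.19), 0.11 for reference genes (AT4G34270 0.30, GAPC2 -0.14), -0.06 for root markers (PYK10 -0.51, EXPA7 0.09) and 0.21 for sugar transport (SWEET10 0.15, SWEET11 0.21). Adjusted over the list alone, 0 members of the lists fixed before the data passed in the unblocked limma fit, and in the blocked fit 2 photosynthesis genes and 1 root marker were lower and 1 sugar transport gene higher, beside the 2 cell cycle genes.

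In inoculated cotyledons, where the comparison asks how infected mutants differ from infected wild type, ECS1 (-3.69 ± 0.43), AT3G47250 (-1.62 ± 0.16) and AT1G67860 (-1.26 ± 0.15) fell in the mean of the alleles. These 3 genes passed in both fits (unblocked adjusted p = 0.0415, 0.0199 and 0.0415; blocked 2.73e-05, 1.87e-04 and 0.00110). AT3G47250 averaged 4.68 in inoculated Ws-2 and 3.04 and 3.09 in the mutants, below the lower quartile of the arrays. In the blocked fit AT3G62950 (-2.49), AT5G03350 (-2.39), AT1G33340 (-2.39), AT3G22240 (-2.31), the thionin gene AT1G66100 (-1.99), ZW9 (-1.97) and AT3G46880 (-1.86) fell. Their blocked adjusted p ran from 5.46e-06 (AT3G62950) to 0.0286 (AT1G66100) and their unblocked one from 0.164 to 0.642. The proline dehydrogenase gene AT5G38710 (-1.14) and AT1G23960 (-0.88), which complete the 5 genes of smallest unblocked p, fell in the blocked fit as well (0.00270 and 0.00493, unblocked 0.126 and 0.0926). Rises in the blocked fit included the late embryogenesis abundant gene LEA4-5 (1.36), AT1G24600 (1.06), AT2G37870 (0.92), the protein phosphatase family gene AT3G05640 (0.88), rps18 (0.83), GH9B8 (0.81), AT1G50290 (0.79), AT1G73630 (0.79) and CLV3 (0.78 ± 0.18). Their adjusted p ran from 0.00493 (rps18) to 0.0424 (AT1G73630), with 0.0154 for CLV3. Taken by experiment, 1 and then 2, the differences were -4.52 and -2.87 for ECS1, -1.49 and -1.75 for AT3G47250, -1.48 and -1.05 for AT1G67860, -2.40 and -2.58 for AT3G62950, and -3.30 and -1.49 for AT5G03350. They were -3.61 and -1 for AT3G22240, -0.94 and -3.04 for AT1G66100, -2.33 and -1.61 for ZW9, 1.05 and 1.68 for LEA4-5, and 0.89 and 0.74 for GH9B8. Over all probe sets 9 fell and 0 rose in the unblocked limma fit (1510 at an unadjusted p under 0.05), against 100 and 44 in the blocked fit. Of these 9, 1 is the probe set without a gene whose fall in water rests mostly on clv1.13. It was at -2.52 ± 0.16 (unblocked adjusted p = 9.08e-04), and at -4.94 between clv1.13 and clv1.12. Without 1 array the unblocked count was 6 without Ws-2 inoculated replicate 2 and 3 or 4 without any of the other 5 inoculated arrays. The blocked count was then 20 (without Ws-2 inoculated replicate 1) to 144, with 59 without Ws-2 inoculated replicate 2, 89 and 43 without clv1.12 inoculated replicates 1 and 2, and 72 without clv1.13 inoculated replicate 1. The unblocked call of ECS1 and of AT1G67860 ended in 11 of 12 such fits and that of AT3G47250 in 6.

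**Figure D2:**
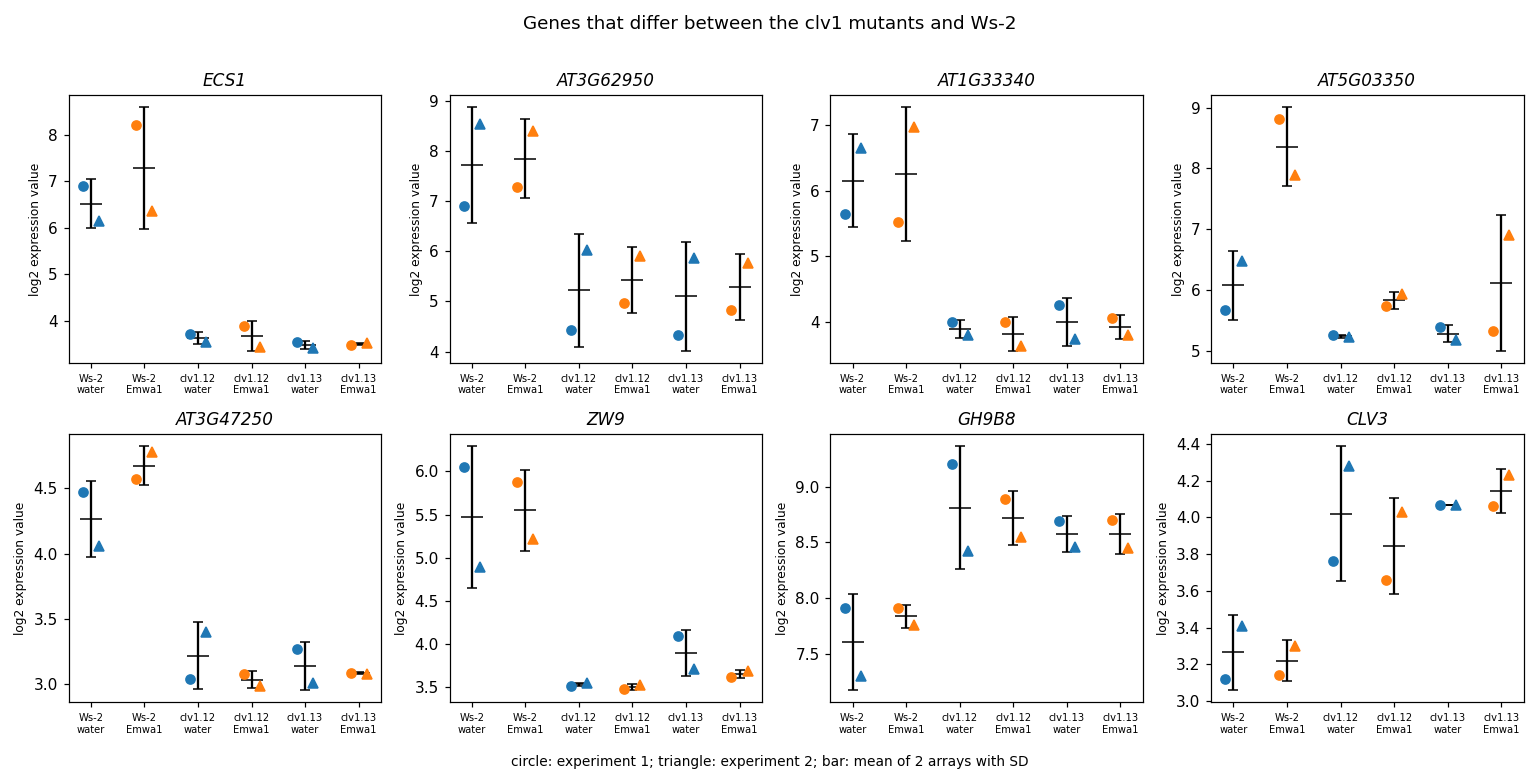
Log2 expression of genes that differed between clv1 and Ws-2 on each of the 12 arrays, by genotype and treatment; circles are arrays of experiment 1 and triangles of experiment 2, blue for water and orange for Emwa1, and bars are the mean of 2 arrays with its SD. ECS1 averaged 6.52 and 7.29 in the water and inoculated groups of Ws-2, 3.64 and 3.68 in those of clv1.12 and 3.49 and 3.51 in those of clv1.13.

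The other defence-associated genes were lower in inoculated clv1 than in inoculated Ws-2, with a median of -0.44 and 2 of 15 above 0 (-0.64 and -0.08 within the experiments). Their adjusted p was 0.00305 (blocked 9.57e-05), but 0.456 with an estimated correlation, 0.745 without Ws-2 inoculated replicate 1 and 0.133 without clv1.12 inoculated replicate 2. AT3G22240 was at -2.31, CHI at -1.21, AT1G35710 at -0.64 and AT1G13470 at -0.44. Plastid-encoded photosynthesis and energy genes were higher, with a median of 0.36 and 42 of 43 above 0 (0.38 and 0.30 within the experiments; adjusted p = 3.45e-16, but 0.456 with an estimated correlation). Of these, petD (0.64) rose in the blocked fit, with psaJ at 0.64, petL at 0.59 and ndhE at 0.90. These means rest mostly on clv1.12: petD differed from Ws-2 by 1.21 in clv1.12 and 0.08 in clv1.13, psaJ by 1.17 and 0.11, petL by 1.17 and 0.00, and ndhE by 1.32 and 0.47. Plastid ribosome and polymerase genes had a median of 0.17 with 15 of 19 above 0 (0.07 and 0.26 within the experiments; adjusted p = 0.00127, but 0.456 with an estimated correlation). rps18 was at 0.83, rpl20 at 0.56, rpl32 at 0.87 and rps14 at 0.42. In clv1.12 and clv1.13 taken alone, rps18 was at 1.37 and 0.30 and rpl32 at 1.84 and -0.09. The 25S ribosomal RNA control was 11.17 and 11.46 on the Ws-2 inoculated arrays, 11.91 and 11.82 on those of clv1.12 and 11.39 and 11.26 on those of clv1.13. The 3' minus 5' control signal there was 2.33 and 2.24, 2.66 and 2.60, and 2.38 and 2.24. The guard cell lineage list was lower (median -0.34; -0.32 and -0.30 within the experiments; adjusted p = 0.0394, but 0.456 with an estimated correlation, 0.0686 in the blocked fit and 0.0713 after quantile normalization). SPCH was at -0.36, FMA at -0.34 and MUTE at -0.16, and its call ended in 6 of the 12 fits that leave out 1 array (highest 0.267, without Ws-2 inoculated replicate 2). Chloroplast ribosomal proteins were lower (median -0.14; -0.10 and -0.11 within the experiments; adjusted p = 0.0394, but 0.456 with an estimated correlation and 0.0916 in the blocked fit), and their call ended in 7 of those 12 fits (highest 0.188, without Ws-2 inoculated replicate 2). Sugar and amino acid transport genes passed in the blocked fit alone (median 0.24; 0.42 and 0.15 within the experiments; adjusted p = 0.0486, but 0.499 in the blocked fit with an estimated correlation, and unblocked 0.304). SAG29 was at 0.95 and SWEET11 at 0.24. In the unblocked fit 23 lists, the sugar list among them, did not pass (adjusted p from 0.0644 to 0.961). Those fixed before the data had medians of 0.46 for abscisic acid and dehydration (LTI30 0.97, COR15A 0.59), -0.35 for the cell cycle (AUR1 -0.44, AUR2 -0.35), -0.16 for endoplasmic reticulum folding (CRT1b -0.18, ATERDJ3B -0.21), and 0.16 for heat shock (ATHSP22.0 0.16, AT1G53540 0.16). They were -0.11 for pattern-triggered immunity (WRKY53 -0.28, BIK1 -0.10), -0.12 for photosynthesis (LHCB4.3 -0.73, PSBW 0.19, with 1 member lower adjusted over the list alone), 0.06 for reference genes (AT4G34270 0.08, AT2G28390 0.06) and -0.10 for root markers (PYK10 -0.46, EXPA18 -0.10). In the blocked fit, adjusted over the list alone, 3 cell cycle, 1 guard cell, 1 photosynthesis and 1 root gene were lower, and 2 dehydration and 2 sugar transport genes higher.

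Each allele was also compared with Ws-2 by itself, to see whether both mutations change the same genes. In the blocked fit on water-treated plants, the largest falls of named genes in clv1.12 and clv1.13 were -2.88 ± 0.50 and -3.03 ± 0.50 for ECS1, -2.50 ± 0.78 and -2.62 ± 0.78 for AT3G62950, and -2.27 ± 0.46 and -2.17 ± 0.46 for AT1G33340. GH9B8 rose by 1.21 ± 0.28 and 0.97 ± 0.28. In inoculated plants ECS1 (-3.61 and -3.78), AT5G03350 (-2.53 and -2.25), AT3G62950 (-2.42 and -2.56) and AT1G33340 (-2.44 and -2.34) fell in clv1.12 and clv1.13 in turn. ZW9 (-1.94 and -1.57), AT3G46880 (-1.89 and -1.80), AT2G33850 (-1.08 and -1.02) and AT3G47250 (-1.05 and -1.13) also fell in both alleles in water. Plastid-encoded rpl32 (1.84), rps18 (1.37), ndhE (1.32) and petG (1.29) rose in inoculated clv1.12. CLV3 (0.93, blocked adjusted p = 0.0192) and AT3G31970 (0.76) rose in inoculated clv1.13, and CLV3 was at 0.63 in inoculated clv1.12 (0.0516). None of these single-allele values passed in the unblocked fit. The unblocked limma fit called 0 probe sets for clv1.12 in water (950 at an unadjusted p under 0.05), 2 for clv1.13 in water and 3 for each allele after inoculation, against 27, 48, 271 and 39 in the blocked fit. Of the probe sets lower in the blocked fit, 15 were shared by both alleles in water (23 and 36) and 24 after inoculation (139 and 31). Independent lists would share 0.0364 and 0.189, and data simulated with no genotype effect but the shared Ws-2 arrays gave means of 0.02 and 0. Of those higher, 3 were shared in water (4 and 12, with 0.00211 for independent lists and 0.02 simulated) and 3 after inoculation (132 and 8, with 0.0464 and 0.06). The simulated data hold independent noise and do not keep these list sizes. Their shared counts therefore cannot tell how many probe sets the Ws-2 arrays alone would make lists of this size share. In the unblocked fit 2 were shared after inoculation and 0 in water (limma; 950 and 1580 at an unadjusted p under 0.05). Across probe sets, which are not independent replicates, the differences of the alleles had a correlation of 0.662 in water and 0.681 after inoculation (simulated 0.501 and 0.5) and a covariance of 0.0341 and 0.0411 (simulated 0.0126 and 0.0125). Both alleles were set against the same 2 Ws-2 arrays per treatment, too few to divide between them, so part of the excess may come from those arrays. Across treatments, which share no array, 33 probe sets were lower in the mean of the alleles in both (47 in water and 100 after inoculation in the blocked fit), where 0.207 would be shared by independent lists. Of those lower in each allele by itself (15 and 24), 13 were shared across treatments, against 0.0158 for independent lists. The treatments share the 2 experiments and the variance estimates of 1 fit, so independent lists may be too low a reference.

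Set against each other, the alleles differed in few transcripts. A probe set assigned to no gene, singled out after its values were seen, was lower in clv1.13 than in clv1.12 in water (-4.95 ± 0.18) and after inoculation (-4.94 ± 0.18). It passed in both fits (unblocked adjusted p = 1.70e-05 and 1.74e-05). By experiment, 1 and then 2, it was at -5.24 and -4.66 in water and -5.12 and -4.75 after inoculation. Another probe set assigned to no gene, chosen in the same way, was higher in clv1.13 by 1.89 ± 0.20 in water (unblocked adjusted p = 0.0636, blocked 3.03e-05) and 2.05 ± 0.20 after inoculation (unblocked 0.0326, blocked 1.09e-05). In the blocked fit rps18 was lower in clv1.13 than in clv1.12 in water (-1.13, adjusted p = 0.00546), and after inoculation so were rpl32 (-1.93, 0.00751), psbI (-1.48, 0.00113), petG (-1.41, 0.00544) and rps3 (-1.24, 0.0105). The 25S ribosomal RNA control was 11.57 and 11.64 in clv1.12 and 11.09 and 11.11 in clv1.13 in water, and 11.91 and 11.82 against 11.39 and 11.26 after inoculation. The 3' minus 5' control signal was 2.23 and 2.24 in clv1.12 against 2.15 and 2.01 in clv1.13 in water. After inoculation it was 2.66 and 2.60 against 2.38 and 2.24. The counts were 1 probe set in water and 2 after inoculation in the unblocked fit, and 3 and 32 in the blocked fit.

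The difference of the infection response between clv1 and Ws-2, which asks whether the mutations alter the response itself, was past the threshold for 1 probe set in the blocked fit. That was rps18, which differed by 1.35 ± 0.24 (blocked adjusted p = 0.0211, unblocked 1.00; 1.26 and 1.44 within the experiments). The unblocked limma fit called 0 probe sets (472 at an unadjusted p under 0.05). The other genes of smallest unblocked p, AT3G23325 (0.89), AT5G15320 (0.92), AT1G50290 (0.73) and AT5G42250 (-0.90), passed in neither fit. AT5G03350, named for its fall in inoculated clv1, had a difference in response of -1.57 ± 0.60 (blocked adjusted p = 0.803; -2.94 and -0.21 within the experiments). Plastid-encoded photosynthesis and energy genes responded more positively in clv1 by camera, with a median difference of 0.40 and 40 of 43 above 0 (0.31 and 0.58 within the experiments; adjusted p = 8.21e-24, but 0.328 with an estimated correlation). petL was at 0.82, ndhE at 1.22, atpI at 0.87 and psaJ at 0.85. The plastid ribosome and polymerase genes had a median of 0.30 with 16 of 19 above 0 (0.28 and 0.43 within the experiments; adjusted p = 1.12e-12, but 0.248 with an estimated correlation). rpoA was at 0.70, rpoC2 at 0.67 and rps3 at 0.73. Both the 25S ribosomal RNA control and the 3' minus 5' control signal were higher in infected clv1.12 as well (values above). The other defence-associated genes responded less in clv1, with a median of -0.48 and 1 of 15 above 0 (-0.68 and -0.15 within the experiments; adjusted p = 0.0115, blocked 2.14e-05, but 0.894 with an estimated correlation). AT3G22240 was at -1.77, AT3G18250 at -0.99, AT1G35710 at -0.63 and AT1G13470 at -0.40. Their call ended in 6 of the 12 fits that leave out 1 array, with the highest adjusted p of 0.994 without Ws-2 inoculated replicate 1. Malectin-like leucine-rich repeat kinases had a median of -0.11 with 8 of 31 above 0 (-0.13 and -0.15 within the experiments, camera adjusted p = 0.0404, but 0.495 with an estimated correlation and 0.216 after quantile normalization). The expression of their members of smallest p lay near or below the lower quartile of the arrays. AT1G07560 was at -0.35, AT3G46350 at -0.28, AT1G51810 at -0.29 and AT1G51790 at -0.28, and their call ended in 8 of those 12 fits (highest 0.391, without Ws-2 inoculated replicate 1). Cytosolic ribosomal proteins had a median of 0.09 with 86 of 117 above 0 (0.16 and 0.01 within the experiments; adjusted p = 5.60e-06, but 0.894 with an estimated correlation, 0.594 after quantile normalization and 0.303 without Ws-2 water replicate 1). Abscisic acid and dehydration genes passed in the blocked fit alone (median 0.37; 0.42 and 0.38 within the experiments; adjusted p = 0.00880, unblocked 0.506, and 0.667 in the blocked fit with an estimated correlation). LTI30 was at 1.32 and COR15A at 0.51. In the unblocked fit 23 lists, the dehydration list among them, did not pass (adjusted p from 0.0803 to 0.989). Those fixed before the data had medians of 0.02 for the cell cycle (AUR3 0.33, AUR2 0.07), 0.03 for endoplasmic reticulum folding (BZIP60 0.09, AT5G07340 0.07), -0.16 for the guard cell lineage (FMA -0.24, SPCH -0.16), and -0.05 for heat shock (AT5G48570 -0.23, ATHSP22.0 0.14). They were 0.02 for pattern-triggered immunity (WRKY6 0.35, EFR 0.15), 0.09 for photosynthesis (PSBW 0.26, RCA 0.23), -0.05 for reference genes (AT4G34270 -0.22, GAPC2 0.16), 0.01 for root markers (EXPA18 -0.04, PYK10 0.05) and 0.03 for sugar transport (SAG29 0.67, SWEET10 -0.14).

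**Figure D3:**
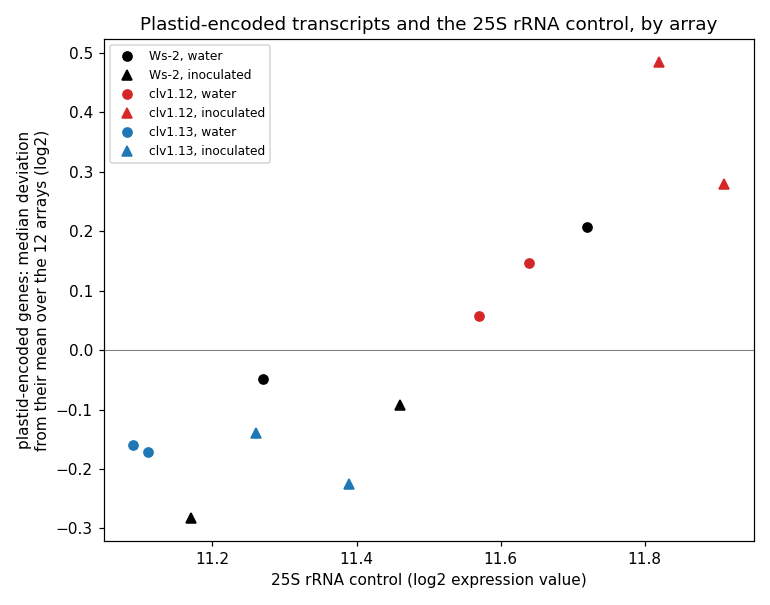
Median deviation of plastid-encoded transcripts on each of the 12 arrays from their mean over all arrays (log2), against the 25S ribosomal RNA control signal of the same array (log2), with 1 point per array. The deviations run from -0.28 on Ws-2 inoculated replicate 1, where the control is at 11.17, to 0.49 on clv1.12 inoculated replicate 2, where it is at 11.82.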

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

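The tests chosen after results were seen are the relation of plastid transcripts to the 25S control and to mitochondrial transcripts, the 3 tests on genes changed in both clv1 alleles and the set of genes they run on (first those called in the mean of the alleles), the splits that part all pairs in the unblocked fit, and the comparison of the alleles' responses.

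The infection response differed between clv1 and Ws-2 for rps18 by 1.35 in the blocked fit, and for 6 gene lists by camera. Their medians were 0.374 for abscisic acid and dehydration genes (blocked fit alone), 0.0875 for cytosolic ribosomal proteins, -0.105 for malectin-like leucine-rich repeat kinases, -0.475 for other defence-associated genes, 0.402 for plastid-encoded photosynthesis and energy genes and 0.295 for plastid-encoded ribosome and polymerase genes. The response also differed between the alleles, clv1.13 minus clv1.12, for the plastid photosynthesis and energy genes by a median of -0.205 (adjusted p = 3.89e-10) and for the plastid ribosome and polymerase genes by -0.455 (adjusted p = 1.15e-09). For the other defence-associated genes it differed in the blocked fit alone by -0.21 (adjusted p = 0.04999, but 0.9925 with an estimated correlation, and unblocked 0.2742). None of these list differences holds with an estimated correlation. The 1 control probe set singled out among those outside the tests was higher in clv1 than in Ws-2 by 2.472 in water and 2.182 after inoculation (blocked adjusted p = 1.52e-04 and 3.76e-04, unblocked 0.0860 and 0.135). What it detects in these plants could not be settled. It lay between 3.54 and 3.89 on the 4 Ws-2 arrays, 5.54 and 6.53 on the 4 clv1.12 arrays and 5.62 and 6.48 on the 4 clv1.13 arrays.

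By camera, plastid-encoded lists were higher in infected clv1.12 and lower in infected Ws-2, but not with an estimated correlation (adjusted p = 0.402 and 0.190 in clv1.12, 0.538 for both in Ws-2). A difference in how much RNA without long poly(A) tails was labelled on each array may account for this. The median plastid deviation followed the 25S ribosomal RNA control over the 12 arrays (r = 0.891, permutation p = 1e-04, adjusted over 3 relations 3e-04, and rho = 0.867, permutation p = 0.00044). The relation was r = 0.848 without the 2 farthest arrays, and 0.879 and 0.921 within the experiments. The permutations shuffle the 12 arrays freely, without regard to genotype, treatment or experiment. Every clv1.12 array lay above every clv1.13 array on both measures. The p-values therefore cannot tell a difference in labelling between arrays from a difference between the groups. A change of all organelle transcripts together stays open: the relation of the mitochondrial median to the plastid one is weak over the 12 arrays (r = 0.0907, permutation p = 0.779; rho = -0.0105; 0.241 without the 2 farthest), but 0.485 and 0.253 within the experiments. RNA degradation stays open too, since the relation to the 3' minus 5' control signal (r = 0.65, permutation p = 0.0225, adjusted 0.0338; rho = 0.394, permutation p = 0.205; 0.528 and 0.891 within the experiments) rests on the 2 farthest arrays and is 0.0805 without them. An effect of the clv1.12 genotype on plastid transcripts itself stays open as well, as untested.

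The genes changed in both clv1 alleles in the blocked fit could reflect chance values of the shared Ws-2 arrays. For values of single arrays this is argued against: of the 15 probe sets lower in both alleles in water, 13 were also lower in both after inoculation. Those are separate arrays (24 probe sets there), and independent lists would share 0.0158. Both treatments share the 2 experiments and the variance estimates of 1 fit, so this reference may be too low. A deviation of the Ws-2 plants of an experiment, common to both treatments, stays open. In Ws-2, AT1G33340 was at 5.65 (water) and 5.53 (inoculated) in experiment 1, and at 6.66 and 6.98 in experiment 2. For the 15 genes called in both alleles in either treatment, a segment within 200 genes of CLV1, carried along with the mutations, is argued against. Of these genes 0 lie there, and of the 13264 tested genes 164. The one-sided Fisher's exact test (p = 1) adds no evidence, since a count of 0 can give no other value. A wider segment was not tested. The other probe sets called in both alleles were not placed. Segments of another background elsewhere stay open: 0 of these 15 genes have another within 20 genes, but the random median is 0 as well (permutation p = 1), so the test cannot decide. An effect of the loss of CLV1 function also stays open, as untested, and so does a difference between the strains from which the mutants and Ws-2 were grown.

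For the mean infection response, chance cannot be excluded from 100 splits of the arrays within genotypes, since 5 of them, the real one included, gave at least the real 17 probe sets in the unblocked fit. The highest other count was 6306, and the 4 other splits as large part 0 of the 6 pairs of an experiment, so they follow the 2 experiments and point to a structure of the samples. Among the 32 splits that part all pairs as the real one does, only the real split gave as many. That was 1 of 32 unblocked (17, highest other 0) and 1 of 32 in the blocked fit (229, highest other 8). These counts argue against chance there but cannot exclude it, since 1 of 32 is the smallest share that these splits can give.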

How the results depend on the processing

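The alternatives were planned, except the blocked counts with 1 array left out and the lists tested in the mean infection effect and between the alleles' responses, which were chosen after the data were seen. With the replicate block the counts became 53 for infection in Ws-2, 41 in clv1.12, 19 in clv1.13 and 229 in the mean of the genotypes. For clv1.12, clv1.13 and their mean against Ws-2 they became 27, 48 and 61 in water and 271, 39 and 144 after inoculation. They became 1 for the difference in response, 3 and 32 for clv1.13 against clv1.12 in water and after inoculation, 18 and 27 for both alleles, and 59 in place of 10 calls of named genes. It also called other defence-associated genes between the alleles' responses (adjusted p = 0.04999, but 0.9925 with an estimated correlation, and 0.2742 without the block). Its median residual standard deviation was 0.144, against 0.183 without the block. With probe sets under the 40th percentile left out, the counts after inoculation were 1 for clv1.12, 2 for the mean of the alleles and 1 for both alleles. Quantile normalization gave 4 for clv1.13 in water and 1 for clv1.13 against clv1.12 after inoculation. A trend with robust hyperparameters gave 5 for clv1.12 and 5 for the mean of the alleles after inoculation, 2 for clv1.13 against clv1.12 in water and 6 calls of named genes. The cause was not tested for these. With only the arrays compared, which leaves fewer arrays for the spread, the counts were 0 for clv1.13 and 0 for the mean of the alleles in water, 0 for clv1.12, 1 for clv1.13 and 1 for the mean after inoculation, and 0 and 1 for clv1.13 against clv1.12 in water and after inoculation. With an estimated correlation 0 of the 24 called lists outside the mean infection effect passed.

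The direction reversed for cytosolic ribosomal proteins in infected clv1.12 after quantile normalization (adjusted p = 0.965), for plastid photosynthesis and energy genes in water without Ws-2 water replicate 2 (0.2907), and for cytosolic ribosomal proteins in infected clv1.13 without clv1.13 water replicate 2 (0.7145). The cause was not tested.

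Leaving out 1 array assumes that the lone array of its group varies like those of the other groups. The counts then ran from 0 to 1 for infection in Ws-2, 0 to 2 in clv1.12, 0 to 0 in clv1.13 and 5 to 49 in the mean. They ran from 0 to 0 for clv1.12, 1 to 1 for clv1.13 and 0 to 1 for their mean in water, and from 0 to 4, 1 to 4 and 3 to 6 after inoculation. They ran from 0 to 1 for the difference in response, 0 to 0 and 0 to 3 for both alleles in water and after inoculation, and 1 to 1 for clv1.13 against clv1.12 in each treatment. There were from 2 to 10 calls of named genes and from 18 to 26 called lists. For the lists that reversed, adjusted p ran from 1.513e-09 to 0.9657 for cytosolic ribosomal proteins in infected clv1.13 and from 2.611e-09 to 0.2907 for plastid photosynthesis and energy genes in water. The blocked counts ran from 6 to 83 for infection in Ws-2, 131 to 292 for the mean, 20 to 108 in water and 20 to 144 after inoculation. The 10 calls of named genes ended 68 times in all over the 12 fits with 1 array left out, so more of these fits ended a call than left it. Genes that had not passed gained a call 7 times, and no named gene reversed. Signal over background limits the genes whose group means lie near or below the lower quartile of the arrays. Among those named are ECS1, ZW9, AT3G47250, AT1G33340, AT1G66100, AT1G23960 and AT5G38710 in the mutants, CLV3 in every genotype and AT1G26380 in the water groups. The malectin-like kinase genes AT1G07560, AT3G46350, AT1G51810 and AT1G51790 are among them in every group. So are BGLU46 and AT1G13470, and AT1G35710 outside inoculated Ws-2.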

Other observations

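The test of the infection response's size by allele and experiment was planned, and the comparison of the experiments was chosen after the data were seen. The 2 experiments differed in more transcripts than genotype or treatment. In experiment 2, 2871 probe sets were higher and 3809 lower (29.4% of those tested), 656 of them by 1 log2 unit or more. AT1G55960 was higher by 4.54, AT2G41250 by 4.44, AT3G55580 by 4.37, AT1G26790 by 4.28 and HYH, a transcription factor of the light response, by 3.10. AT4G16146 fell by 3.34, AT3G62550 by 3.26 and the cold- and dehydration-responsive genes COR15A and COR15B by 2.83 and 2.79. The abscisic acid and dehydration list had a median of -2.25 (adjusted p = 1.19e-05, but 0.729 with an estimated correlation), and the photosynthesis list 0.27 (adjusted p = 2.44e-05, but 0.729 with an estimated correlation). The other defence-associated genes had a median of -0.55 (adjusted p = 5.34e-04, but 0.768 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.10 and plastid-encoded photosynthesis and energy genes 0.15. By camera both had adjusted p = 5.34e-04, but 0.768 with an estimated correlation.

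Genes of lists too small to test gave these differences for infection in Ws-2: 0.11 for DFR and 0.02 for UF3GT of anthocyanin synthesis, -0.48 for GI of the circadian clock, -0.57 for ARR15 and -0.55 for RR16 of the cytokinin response, 0.20 for THI2.1 of the jasmonate list, 1.23 for GRX480 and -0.08 for SAG101 of the salicylic acid list, and -0.22 for SAG29 of the senescence list. None of these 9 passed in either fit (GRX480: blocked adjusted p = 0.0545).

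A weaker infection response in both alleles was tested as a hypothesis over the 220 probe sets that rose in the mean of the genotypes in the blocked fit. The median difference of the response, clv1 mean minus Ws-2, was -0.136, but it was not below 0 throughout: -0.01 and -0.03 for clv1.12 and -0.5 and 0.115 for clv1.13 in experiments 1 and 2. A single array may decide it, since the median was 0.274 without Ws-2 inoculated replicate 1, 0.08 without clv1.12 inoculated replicate 2 and -0.533 without Ws-2 inoculated replicate 2.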
